A study of Mus musculus with 12 samples.

How the data were processed

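RNA was extracted from pancreas of male C57BL/6J mice with TRIzol and an RNeasy column, had an RNA integrity number above 8, and was made into libraries with the Illumina mRNA Prep kit and sequenced as read pairs on a NovaSeq, per the labels' protocols. Tissue was collected every 4 h in the dark, per the labels. The deposited table holds whole-number counts per gene symbol for 12 libraries. Reads were aligned with STAR and counted with HTSeq against GRCm38 (mm10), per the submitters' processing notes, which give no versions. The name of the deposited workbook refers to featureCounts, another counting tool, so which of the tools made the counts is in doubt. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so counts of genes with close relatives or with an antisense partner are uncertain.

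The table had 40840 genes, of which 39350 (96.4%) matched a symbol in the RefSeq annotation of GRCm38.p6, the build from which positions are printed. Totals were 1030189 to 1404038 counts in 11 libraries and 2918805 in the library labelled Young 4 h. A floor of 3 counts equals 2.25 to 3.15 CPM in the 11 and 0.684 CPM in Young 4 h. Intervals and floors cover counting error only. Libraries were checked for copies of one another over genes with 10 or more counts, and the closest pair of the 66, Young 20 h and Young 24 h, differed by a chi-square of 2.9 per gene.

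Groups and times were taken from the labels, and all 12 library columns were mapped to a sample. Genes were kept by filterByExpr with age as the group, which left 5808, and scaled by TMM. edgeR 4.0.16 in R 4.3.3 fitted quasi-likelihood models with age and the cosine and sine of a 24 h period, and called genes at a Benjamini-Hochberg adjusted p under 0.05. The age test took the age term, the shared rhythm test the cosine and sine terms together, and 1 fit with a curve for each age gave the rhythm in Young, the rhythm in Old and their interaction. Both ages share 1 estimate of spread in each fit. Amplitudes are the distance from the mean of the curve to its peak in log2 units. Amplitudes and peaks of single ages with standard errors came from least squares fits to log2 CPM with a prior count of 2, over 6 libraries of each age.

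The tests, the 48 gene lists and the rule for named genes were fixed before the data were examined. The rule took up to 12 genes in each direction of age that passed, had a mean of at least 1 CPM and lay on the same side at every time compared, the 10 genes with the smallest p in each rhythm test, every core clock gene, and up to 4 members of each list described; predicted genes were passed over. Genes named outside it are said to be so, and some genes that the rule takes are not reported here. Lists with at least 3 tested members, 31 of the 48, were tested for age with camera at a preset correlation of 0.01, with an estimated correlation and with fry, and for rhythm against the 60 distinct orders of the 6 times. Of the 48, 17 had too few tested members. Lists of central neurons, central glia, hypothalamic peptides, peripheral nerves and ganglia, fibroblast markers outside the matrix, collagens with Sparc, and beta cell genes other than hormones were written after the first results were seen.

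Alternatives fixed in advance were RLE scaling, scaling without digestive enzymes, no filter, a stricter filter of at least 1 CPM in at least 6 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), no time term, a curve for each age, collection time as a block, times as a factor, separate fits of each age, and leaving out each library in turn. Fits without both 4 h libraries, without Young 4 h and Old 24 h, with the other tools or no time term without Young 4 h, and with each remaining library also left out (for the curve difference within lists too) were chosen after seeing the data. DESeq2 values that it set to missing were left missing. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

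The fits were tested on simulated counts in which 200 genes were changed, 100 of each size. No simulated library stood apart from the rest as Young 4 h does in the data. With 12 libraries, the age test recovered 39% at a log2 fold change of 1 and 98% at 2, the shared rhythm test 66% at a log2 amplitude of 1 and 100% at 2, the Young test 24% and 93%, and the Old test 21% and 93%. The interaction test recovered 6% of genes with opposite curves of amplitude 0.5 in each age and 62% at amplitude 1. Without Young 4 h these shares were 66% and 100% for age, 96% and 100% for the shared rhythm, 80% and 100% in Young, 76% and 100% in Old, and 39% and 94% for the interaction. False calls were 2.9 to 7.1% of calls with 12 libraries and 5.7 to 6.7% without Young 4 h. The estimated biological coefficient of variation fell from 0.308 in 12 libraries to 0.176 without Young 4 h.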

Results

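Polyadenylated RNA of whole pancreas was sequenced from male C57BL/6J mice, a common inbred laboratory strain, killed at 5 months (Young) or 25 months (Old) after 4 weeks of single housing on a light-dark cycle. Each age had 6 libraries, 1 at each collection time of 4, 8, 12, 16, 20 and 24 h, labelled in zeitgeber time, so no time was repeated within an age. Tissue was collected in the dark, and how long mice had been in darkness is not given in the sources used here, so peak hours below are on the labelled scale. The design asks which transcripts follow a 24 h curve, whether that curve differs between ages, and which transcripts differ in level with age. The library labelled Young 4 h held 2918805 counts and the other 11 held 1030189 to 1404038, although the protocol aimed at 40M or more reads per library. A single count was therefore 0.749 to 1.05 CPM (counts scaled to library size) in the 11. Of 40840 genes counted, 28805 had a count and 5808 had enough counts to be tested in all 12 libraries. The labels do not say whether a library came from 1 mouse, so single libraries are the units. With no time repeated within an age, p-values measure the spread of libraries about the fitted curve. That spread also holds departures from a 24 h cosine and, in fits of a shared curve, differences in the curve between ages.

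The library labelled Young 4 h was rich in neural transcripts that were near the detection floor in the rest. Snap25, which serves synaptic vesicle fusion, stood at 243 CPM against at most 2.58 CPM in any other library, and Syt1, a calcium sensor of synaptic vesicles, at 219 CPM against at most 1.05. Slc1a2, the glutamate transporter of astrocytes, stood at 345 CPM against at most 5.26, and Mobp, a myelin gene of the brain, at 214 CPM against at most 3.48. Its digestive enzyme genes took 19.51% of counts (95% Wilson interval, counting error only, 19.46 to 19.56%), against 33.89 to 47.2% in the other 11. Its correlation of log2 CPM with other libraries was 0.66 to 0.675, against 0.879 to 0.934 among the 11. The Y-linked gene Ddx3y stood at 16.7 to 47.6 CPM in all 12 libraries, and Xist, the transcript of the inactive X chromosome, had 18 counts in Young 4 h and at most 1 in each of the others. The count of genes past each test is therefore given for all 12 libraries, as fixed before the data were examined, and again for the 11 libraries without Young 4 h. Leaving out each library in turn was also fixed then, and the choice to report this 1 throughout was made after its values were seen.

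**Figure D1:**
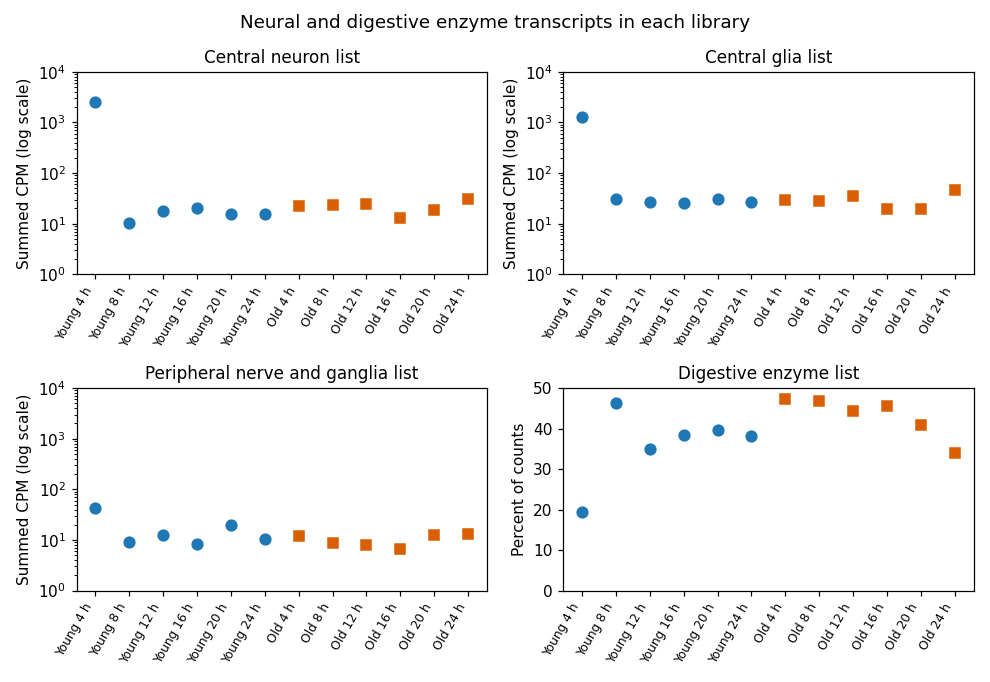
Summed CPM per library (log axis) of 20 central neuron genes, 15 central glia genes and 15 peripheral nerve and ganglion genes, with the 30 digestive enzyme genes beside them. The library labelled Young 4 h stands at 2539 CPM for neurons and 1259 CPM for glia, against at most 31.2 and 46.9 CPM in the other 11 libraries.

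Genes of the molecular clock followed a 24 h curve that both ages shared. In all 12 libraries 9 genes passed the test of the shared curve, and 7 of them were core clock genes, among them Nr1d2, Per1, Arntl, Tef, Per2 and Per3. The other 2 were Usp2, which encodes a deubiquitinase and is a known clock output, and Ypel2. Arntl, which encodes the activator BMAL1, had a log2 amplitude of 2.77 ± 0.28 (SE, n = 6) in Young with its peak at 22.9 ± 0.4 h. In Old its amplitude was 2.71 ± 0.29 (n = 6) with the peak at 23.5 ± 0.4 h. Arntl had 0 counts in Young 8 and 12 h and at most 1 in Old 8 and 12 h. The prior count of 2 therefore sets its troughs, and these amplitudes and their errors depend on it. By edgeR its amplitudes were 3.33 in Young and 3.16 in Old, and 4.285 and 2.88 without Young 4 h. The Young least squares fits in this paragraph include Young 4 h. Nr1d2, which encodes the repressor REV-ERB beta, peaked at 9.8 ± 0.3 h in Young with an amplitude of 1.98 ± 0.16 and at 10.3 ± 0.1 h in Old with an amplitude of 1.33 ± 0.04. Per1, which also encodes a clock repressor, peaked at 11.2 ± 0.5 h in Young and at 11.6 ± 0.7 h in Old, with amplitudes of 1.63 ± 0.21 and 1.81 ± 0.33. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 5808 genes, adjusted p was 0.000508 for Nr1d2, 0.00117 for Per1, 0.00145 for Arntl, 0.0303 for Tef, 0.04 for Per2 and for Usp2, 0.0447 for Per3 and 0.0497 for Ypel2. Of 19 core clock genes with a symbol among those counted, 12 were tested, 7 passed over all genes and 9 passed adjusted over the list alone, which added Clock and Cry1. Npas2, Nr1d1, Dbp, Hlf, Nfil3, Bhlhe41 and Ciart had too few counts to be tested.

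**Figure D2:**
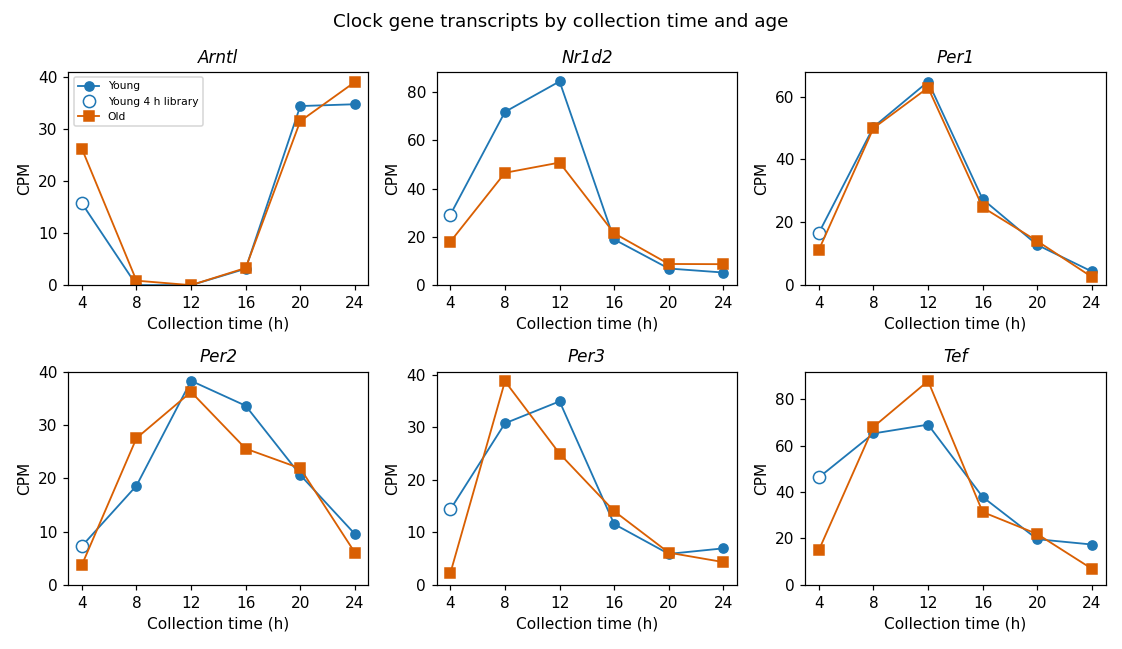
CPM of clock genes by collection time in h, with Young in blue and Old in orange and 1 library per point; the open circle is the library labelled Young 4 h. Arntl reached its highest values at 20 and 24 h and Nr1d2 at 8 and 12 h at both ages.

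Without Young 4 h, 87 of 5852 genes passed the test of the shared curve, and they included all 9 above. Of the 12 tested core clock genes 9 now passed over all genes, with Clock (log2 amplitude 0.59, adjusted p = 0.0223 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Cry1 (0.99, adjusted p = 0.0396), and 11 passed adjusted over the list alone. The calls of Nr1d2, Per1, Tef, Per2 and Per3 held whichever of the 11 was left out. Arntl passed in the 8 fits that tested it, but it was not tested without Old 4, 20 or 24 h, where it was high in Old. Clock lost its call without Young 8 h or Old 8, 12 or 20 h (adjusted p of 0.0894 at most). Cry1 lost it without Young 8 or 16 h or Old 4, 8, 12, 16 or 20 h (0.224) and Usp2 lost it without Old 12 h (0.0655). Of 21 tested genes of the unfolded protein response list, chaperones and folding factors of the endoplasmic reticulum among them, 6 passed over all genes and 10 adjusted over the list alone. In all 12 libraries 0 passed over all genes by edgeR (Creld2 and Hyou1, adjusted p = 0.0538, Hsp90b1 0.0823 and Hspa5 0.125; all 4 passed by DESeq2, at 0.00225 or below), 10 had an unadjusted p under 0.05 and 6 passed adjusted over the list alone. In the 11, Creld2 (log2 amplitude 0.84, adjusted p = 0.00028), Hyou1 (0.71, 0.000817), Hsp90b1 (0.74, 0.000894) and Hspa5, which encodes the chaperone BiP (0.78, 0.00197), peaked at 17.3 ± 0.5, 17.3 ± 0.5, 18 ± 0.7 and 17 ± 0.8 h (SE, n = 11). Wars, the tryptophan transfer RNA ligase gene (adjusted p = 0.35 in 12 libraries), peaked at 5.3 ± 0.4 h with an amplitude of 0.85 (adjusted p = 2.92e-05). Each of these 5 genes passed whichever of the 11 libraries was left out.

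Among genes that respond to glucocorticoids, 5 of 9 passed over all genes and 8 adjusted over the list alone in the same 11 libraries, against 1 (Per1) and 7 in all 12. The metallothionein gene Mt1 had a log2 amplitude of 1.65 with its peak at 6.0 ± 1.0 h (adjusted p = 0.00634 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, had an amplitude of 1.32 with its peak at 12.6 ± 1.3 h (adjusted p = 0.00634). Mt1 and Fkbp5 did not pass in 12 libraries by edgeR (adjusted p = 0.35 and 0.131), and DESeq2 called Fkbp5 there (0.00397). Of 7 heat shock genes 2 passed over all genes and 3 adjusted over the list alone without Young 4 h, led by Hspa8 (amplitude 0.77, adjusted p = 0.00393, peak at 15.5 ± 0.9 h). With Young 4 h kept, 0 of the 7 passed by edgeR either way, 0 had an unadjusted p under 0.05, and Hspa8 had an amplitude of 0.28 (adjusted p = 0.802). Mt1 lost its call without Young 8 h or Old 4 h (0.0621 at most), Fkbp5 without Young 12 h or Old 12 h (0.162) and Hspa8 without Old 16 h (0.0914). None of 24 digestive enzyme genes passed by edgeR in 11 or 12 libraries, over all genes or adjusted over the list alone. In 11, 2 had an unadjusted p under 0.05 and the median log2 amplitude was 0.12, and in 12, 1 did and it was 0.19.

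Islet hormone genes followed collection time too. In the 11 libraries the insulin genes Ins1 (log2 amplitude 1.71, adjusted p = 0.00328 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Ins2 (1.57, 0.0129) passed the shared test. So did the amylin gene Iapp (1.98, 0.000894), the glucagon gene Gcg (1.51, 0.0101) and the granule gene Chga (1.84, 0.000894). The shared curve of all 5 peaked between 15.4 and 15.8 h (SE of 0.7 to 1.1 h), but fits by age were further apart. Without Young 4 h, Ins1 peaked at 16.7 ± 0.6 h in Young and 13.7 ± 1.3 h in Old. Ins2 peaked at 16.5 ± 0.7 and 13.6 ± 2 h, and Gcg at 17 ± 0.6 and 13.7 ± 0.8 h. Iapp peaked at 15.8 ± 0.8 and 14.7 ± 1 h, and Chga at 16 ± 0.7 and 15.1 ± 1.7 h. Ins2 stood at 440 CPM at 16 h and 25.2 CPM at 24 h in Young, and at 485 and 14.8 CPM in Old. Of the 5 tested beta cell genes 3 passed over all genes and 4 adjusted over the list alone, and of 3 pan-endocrine genes 2 and 2. In all 12 libraries none of these passed the shared test by edgeR (Iapp, adjusted p = 0.0538, to Chga, 0.84), while DESeq2 called Iapp, Ins1 and Gcg and limma-voom Iapp, and 4 beta cell genes and 0 pan-endocrine genes passed adjusted over the list alone. Leaving Old 16 h out of the 11 ended the call of Ins2 (adjusted p = 0.174) but not those of Ins1, Iapp, Gcg and Chga, whose adjusted p stayed at 0.049 or below whichever of the 11 was left out. Gcg was chosen for this group after its values were seen.

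**Figure D3:**
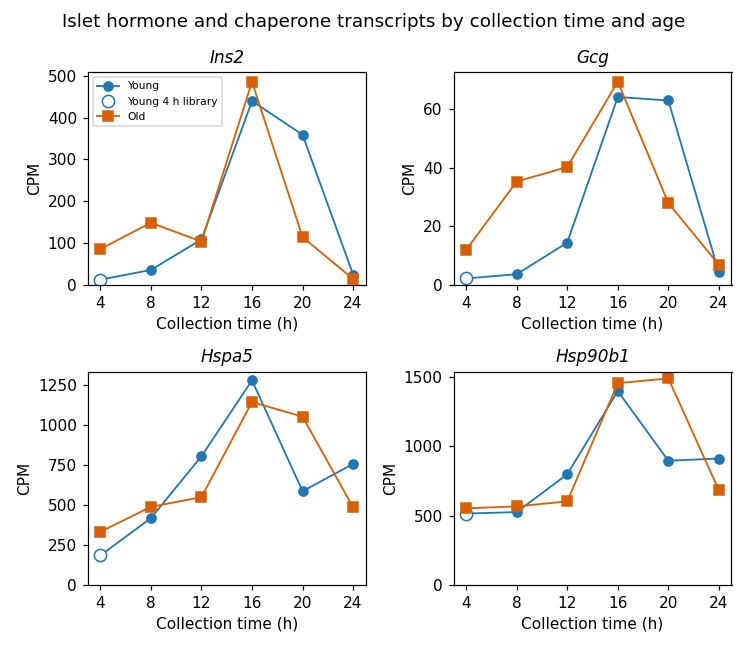
CPM of the hormone genes Ins2 and Gcg and of the chaperone genes Hspa5 and Hsp90b1 by collection time in h, with Young in blue, Old in orange and 1 library per point; the open circle is the library labelled Young 4 h. In Old each of the 4 genes stood higher at 16 h than at 4 h. The same held in Young, but there the 4 h point is the library rich in neural transcripts. Its unfolded protein response and beta cell list sums (2472 and 153 CPM) were the lowest of the 12, so the Young contrast says little about time.

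The other tools called 40 (DESeq2) and 8 (limma-voom, not Per3 at an adjusted p of 0.0698 or Ypel2 at 0.0672) genes in 12 libraries, and without Young 4 h 58 and 71, of which 55 and 68 were among edgeR's 87. In 12 libraries the count fell from 9 to 4 without any 1 of Young 8, 12, 16 or 24 h or Old 12, 20 or 24 h. From the 87 it went to 37 without Old 4 h, 41 without Old 8 h, 43 without Old 12 h, 51 without Old 16 h and 49 without Old 20 h. As groups, the real order of times ranked 1 of 60 possible orders in 12 libraries for the core clock, clock output, glucocorticoid, unfolded protein response and cholesterol synthesis lists. In 11 it did so for the core clock, clock output, glucocorticoid, beta cell, oxidative stress and pancreatic cancer lists. Rank 1 is a share of 0.0167, the smallest possible. Adjusted by Benjamini-Hochberg over 31 lists it was 0.103 in 12 libraries and 0.0861 in 11, so no list passed. With 60 orders a list could pass only if many others ranked first too, so this says little against any single list.

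Within each age, clock genes and, in Young, islet genes had the smallest p. In Young, Nr1d2 (adjusted p = 0.00372 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Gcg (0.00459) and Ins1 (0.0312) passed in the fit of all 12 libraries. In Old no gene passed there by edgeR, 201 had an unadjusted p under 0.05 where chance gives 290, DESeq2 called 4 and limma-voom 0. The smallest adjusted p by edgeR was 0.106, for Nr1d2, Per1 and Tef. With Young 4 h left out, 10 genes passed in Young and 44 in Old. The 10 in Young were Nr1d2, Arntl, Per1, Tef, Ins1, Ins2, Iapp, Gcg, Chga and Gm5771, a predicted gene named here because the list is short, and 9 of the 10 were also among the 44, where independent lists would share 0.0752. In Old the 44 also held Creld2 (log2 amplitude 0.97, adjusted p = 0.00192), Hyou1 (0.82, 0.00607), the kinase gene Pim3 (1.26, 0.00606) and the antigen presentation gene H2-Aa (1.74, 0.0044). In Old, leaving out Old 24 h, a library rich in immune transcripts, ended the calls of H2-Aa (adjusted p = 0.146), the immunoglobulin gene Ighm (0.696) and, like leaving out Old 8 or 16 h, that of Igkc (0.721 at most). Ins1 lost its call in Old without Old 16 h (0.327) and Gcg without Old 16 or 24 h (0.133 at most), while Creld2 kept it whichever of the 11 was left out.

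These counts moved with single libraries. For rhythm in Young the 3 became 10 without Young 4 h, 318 without Young 8 h and 435 without Young 24 h, and the 10 became 21 without Young 24 h. In Old the 0 became 44 without Young 4 h and 4 without Young 24 h. The 44 became 20, 29 or 24 without Old 16, 20 or 24 h and 78 or 77 without Young 8 or 24 h. DESeq2 and limma-voom called 45 and 3 in Young with 12 libraries, 4 and 7 with 11, and 20 and 27 in Old with 11.

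No gene's curve differed between ages by edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment, in 12 libraries or without Young 4 h. In 12 libraries 274 genes had an unadjusted p under 0.05 where chance gives 290 (smallest adjusted p = 0.947). Without Young 4 h 238 did where chance gives 293 (smallest adjusted p = 0.087). DESeq2 and limma-voom also called 0 in both sets. Gcg came closest in both sets (unadjusted p = 0.000328 and 1.49e-05). It peaked at 17 ± 0.6 h in Young with a log2 amplitude of 2.32 ± 0.35 (SE, n = 6), and at 13.7 ± 0.8 h in Old with an amplitude of 1.37 ± 0.30 (n = 6). In the 11 libraries Enpp2, which encodes autotaxin (adjusted p = 0.188), and Ins1 (0.374) followed. Adjusted over the list alone, 2 of 5 beta cell genes (Ins1 and Ins2), 4 of 13 fibroblast genes (Col3a1, Col5a1, Dcn and Col1a1), 4 of 8 complement genes, 2 of 4 MHC class II genes (H2-Aa and H2-Eb1) and 1 of 5 regenerating genes passed there, against 0 over all genes. Over 12 libraries, also with 0 over all genes, these counts were 2 of 5, 5 of 12, 2 of 7, 0 of 4 and 1 of 4, and 2 of 3 pan-endocrine genes (Scg2 and Cpe) passed. Those 2 had 1620 and 1146 counts in Young 4 h, against at most 40 and 26 in any other library, and without it 0 of the 3 passed by edgeR (2 with an unadjusted p under 0.05). The counts in 11 moved with single libraries, of which Old 24 h stood apart for MHC class II (456.4 CPM, next Old library 143.9) and complement (1011 CPM, at most 538 in any other) and Old 16 h held the lowest MHC class II sum of all. Without Old 24 h neither H2-Aa nor H2-Eb1 passed, and 1 MHC class II gene and 1 complement gene did. MHC class II gave 0 without Young 12 or 16 h and 4 without Old 4 or 12 h. Complement gave 1 without Young 12 h or Old 16 h, 2 without Young 16 h and 5 without Old 12 h. The fibroblast count was 0 without Young 16 h or Old 16 h, 9 without Old 4 h and 10 without Old 12 h. The beta cell count was 1 without Young 20 h and 3 without Young 8, 16 or 24 h or Old 12 or 16 h. The regenerating count was 0 without any 1 of the 5 Young libraries and 2, 4 and 3 without Old 12, 16 and 20 h. Over all genes, 2 beta cell genes passed without Old 12 h and 1 without Old 16 h. So did 1 fibroblast gene without Old 4 h and 1 complement gene without Old 12 h. In 12 libraries Frmd6, Kitl, Ptpn18, Dab2, Pqbp1, Fabp5, Klf4, Terf2ip and Ccdc80 had the next smallest p, each with an adjusted p of 0.947. Over the 12 tested clock genes the median log2 amplitude was 1.08 in Young and 1.34 in Old, it was larger in Old for 7 of them, and the peak came a median of 0.5 h later in Old. Simulated genes with opposite curves of log2 amplitude 0.5 at each age were recovered in 6 of 100 cases with 12 libraries and 39 of 100 with 11, so a difference of that size was mostly not detectable with these libraries.

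Reg2, Reg3a and Reg3b, of a family of secreted proteins of acinar cells that are induced in injury and inflammation, were far higher in Old. Young 4 h left out, Reg2 stood at 73.4 ± 23.1 CPM in Young (SD, n = 5) and 2005 ± 1689 CPM in Old (n = 6), a log2 fold change of 4.35 ± 0.58 (SE). Reg3a rose by 4.87 ± 0.66 from 1.61 ± 1.02 to 67.6 ± 59.3 CPM, and Reg3b by 2.78 ± 0.45 from 29.9 ± 19.9 to 280 ± 243 CPM. Each was higher in Old at 4 of 5 shared times: Old 20 h, with 37.7 CPM of Reg2, 0 counts of Reg3a and 19.3 CPM of Reg3b, lay within or below the Young range. Adjusted p was 0.000123 for Reg2 and Reg3a and 0.00187 for Reg3b by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 5852 genes. These genes lie side by side on chromosome 6 (GRCm38.p6; Reg3a at 78380709 to 78383839 and Reg2 at 78405155 to 78408099) and are related in sequence, so counts of reads they share are uncertain. In all 12 libraries Reg2 (4.73, adjusted p = 0.0666) and Reg3b (3.12, adjusted p = 0.402) missed the threshold by edgeR and passed by DESeq2 (adjusted p = 6.26e-06 and 0.0285). Reg3a had too few counts there to be tested under the main filter. Reg3d, a further member, had a log2 fold change of 0.53 without Young 4 h with an adjusted p of 0.752. In the same 11 libraries some of these genes also passed edgeR's quasi-likelihood test of a 24 h curve. Reg3a passed for the shared curve (adjusted p = 0.0359) and in Old (0.0272), and Reg3d in Old (0.03). Reg2 (0.566 shared, 0.395 in Old) and Reg3b (0.0763 and 0.1) passed neither.

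Other genes higher in Old included the long noncoding RNA gene 1810007D17Rik, Kcnma1, Cobl, Camk2b and Itih4. 1810007D17Rik, on chromosome 19 (58606329 to 58629753), was the 1 gene past the threshold in all 12 libraries, with a log2 fold change of 2.39 ± 0.30 (SE, adjusted p = 0.00616 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and higher values in Old at 6 of 6 times. Its function is not given in the sources used here. Young 4 h apart, it rose by 2.31 ± 0.26 from 14.4 ± 11.6 to 62.8 ± 17.8 CPM (SD, n = 5 and 6). In the 11 libraries Kcnma1, the gene of a calcium-activated potassium channel, rose by 2.89 ± 0.39 from 2.54 ± 1.86 to 17.8 ± 5.58 CPM on 0 to 5 counts per Young library (adjusted p = 0.000123 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cobl, an actin nucleator gene, rose by 1.49 ± 0.21 from 22.7 ± 10.1 to 59.2 ± 10.0 CPM (0.000171) and the kinase gene Camk2b by 0.79 ± 0.17 from 48.6 ± 8.73 to 84.1 ± 17.3 CPM (0.0371), and each of the 3 was higher at 5 of 5 times. Kcnma1 stood at 61.3 CPM and Camk2b at 155 CPM in the library labelled Young 4 h, and both are also neuronal genes; with it included their log2 fold changes were 0.84 and 0.41 and neither passed. Itih4, a plasma protein gene of the acute phase, rose by 1.70 ± 0.32 at 4 of 5 times (0.0117). 1810007D17Rik met the values of the rule for named genes but was passed over for its Rik name, as predicted genes were, and Itih4 lay outside the rule. Both were chosen after their values were seen.

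Genes lower in Old included collagen and matrix genes. In the same 11 libraries Col3a1, the gene of type III collagen, fell by 1.31 ± 0.23 on the log2 scale (SE; 135 ± 20.4 to 64.7 ± 37.7 CPM, SD, n = 5 and 6; adjusted p = 0.00607 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The matrix protein gene Sparc fell by 1.16 ± 0.24 (60.5 ± 17 to 27.4 ± 11.7 CPM, adjusted p = 0.0252), and both were lower at 5 of 5 times. The size of the fall of Col3a1 varied with time, from 21 counts in Old 16 h to 149 in Old 24 h. Col3a1 also passed edgeR's test of rhythm in Old (log2 amplitude 1.12, adjusted p = 0.00763) but not in Young (0.18, 0.966). Its difference in curve between ages did not pass (0.696). Ugt2b34, a glucuronosyltransferase gene with 9 to 14 counts per Young library and 0 to 5 per Old library, fell by 2.74 ± 0.52 (adjusted p = 0.0117). The trypsinogen gene Try10, whose close relatives can share reads with it, fell by 0.74 ± 0.15 (226 ± 38.8 to 133 ± 25.7 CPM; adjusted p = 0.0187). Col1a1 (−1.04, adjusted p = 0.0893) and Col1a2 (−0.97, adjusted p = 0.228) missed the threshold over all genes. In all 12 libraries Col3a1 (−0.95, adjusted p = 0.784), Sparc (−1.66, adjusted p = 0.412) and Try10 (−0.51, adjusted p = 0.79) did not pass by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and Ugt2b34 was not tested. DESeq2 called Sparc in the same 12 (−1.65, adjusted p = 0.0151) and neither Col3a1 nor Try10. Sparc stood at 244.81 CPM in the library labelled Young 4 h, against at most 84.33 CPM in the other Young libraries, which enlarges its fall in the 12.

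**Figure D4:**
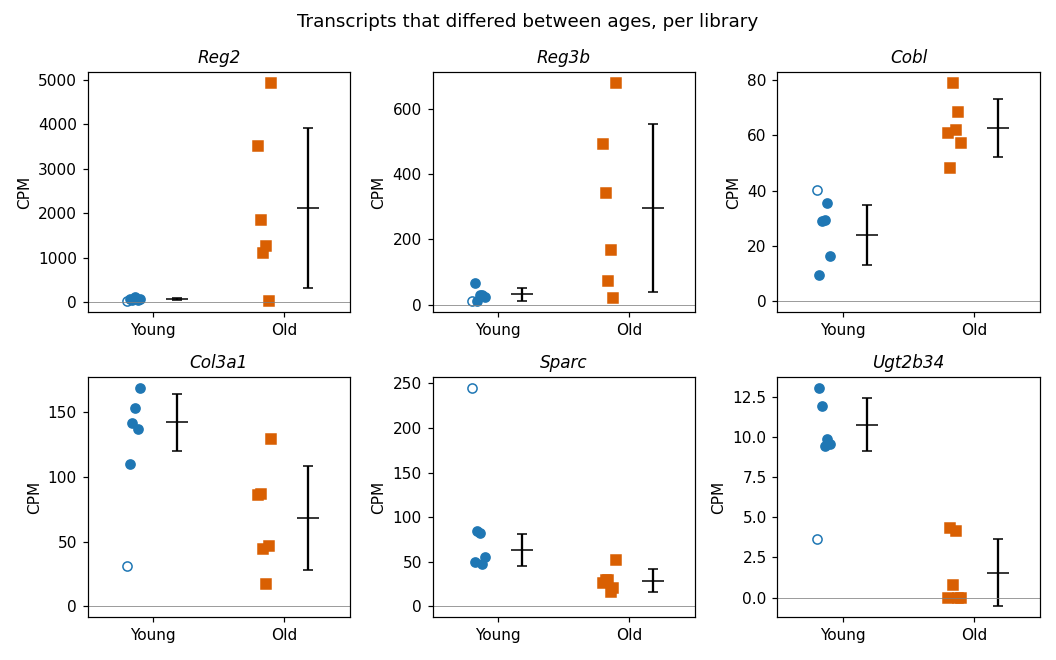
CPM per library, scaled over 12 libraries, of genes that passed the age test without Young 4 h, with Young in blue and Old in orange; the open circle is the library labelled Young 4 h and black bars are the mean ± SD of the other libraries (n = 5 Young, 6 Old). Cobl is higher in each Old library than in each of the 6 Young libraries, and for Reg2 the Old 20 h library, at 37.7 CPM, lies among the Young.

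In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1 gene with age in 12 libraries, higher in Old, and 12 without Young 4 h, of which 8 were higher and 4 lower in Old. In these sets 337 and 360 genes had an unadjusted p under 0.05 where chance gives 290 and 293. DESeq2 and limma-voom called 5 and 1 in 12 libraries, and 14 and 10 without Young 4 h, of which 9 and 9 were among edgeR's 12. The 5 of DESeq2 were 1810007D17Rik, Reg2, Reg3b, Itih4 (adjusted p = 0.00443) and Sparc. In 12 libraries edgeR called Reg2 with no time term (adjusted p = 0.0257) and with a curve for each age (0.0271), and with no low count filter it called these 5, Reg3a and Cobl among others. With the filter of at least 1 CPM in at least 6 libraries it called Reg2 (0.0345) and Reg3a (5.32, adjusted p = 0.0186) but not Reg3b (0.219). In the 11 libraries Itih4 did not pass by DESeq2 (adjusted p = 0.186) or limma-voom (0.124), nor Reg3a (0.771) and Camk2b (0.0503) by limma-voom, and DESeq2 set Kcnma1 and Ugt2b34 to missing. Col3a1 did not pass with no time term (−1.06, adjusted p = 0.289), and Camk2b (0.105) and Sparc (0.0892) did not without both 4 h libraries. With time as a block and both 4 h libraries left out, Sparc passed (−1.13, adjusted p = 0.0387) and Camk2b did not (0.109). In 12 libraries the 1 became 5 without Old 20 h, and in 11 the 12 became 5 without Old 12 h. Of the 12, Reg2, Reg3b, 1810007D17Rik, Kcnma1 and Cobl passed whichever of the 11 libraries was left out. Reg3a passed in the 6 of 11 fits that tested it, but it was not tested without Old 4, 8, 12, 16 or 24 h. Those are the libraries where it was high (33 to 182 counts, against 0 in Old 20 h), so its dependence on them is not known. Col3a1 lost its call without Old 12 h or Old 20 h (highest adjusted p = 0.0707), Itih4 without Young 8 or 24 h or Old 12 or 16 h (0.108) and Ugt2b34 without Young 8 or 24 h or Old 12 h (0.106). Camk2b, Sparc and Try10 passed in 4, 4 and 5 of 11 fits. Camk2b lost its call without Young 8, 12 or 24 h or Old 4, 8, 12 or 20 h (0.19). Sparc lost it without Young 12 or 24 h or Old 4, 8, 12, 16 or 20 h (0.16) and Try10 without Young 8, 16 or 24 h or Old 8, 12 or 20 h (0.179).

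As groups, 3 of 31 tested lists passed camera with age without Young 4 h. Genes of fibroblasts and stellate cells, the connective tissue cells of the pancreas, were lower in 12 of 13 cases (median log2 fold change −0.59, adjusted p = 3.87e-09; adjusted p = 0.892 with an estimated correlation). Of these, 2 passed over all genes and 7 adjusted over the list alone: Col3a1, Fn1, Col6a3, Dpt, Col1a2, Sparc and Col1a1. The summed CPM of that list spanned 173.4 in Old 16 h to 799.9 in Old 24 h, against 549.6 to 894.8 in the 5 Young libraries. Regenerating and acute phase genes were higher in 4 of 5 cases (median 2.78, adjusted p = 0.00048; adjusted p = 0.892 with an estimated correlation), with 3 passing over all genes and 4 adjusted over the list alone. Genes of cytosolic ribosomal proteins were higher in 27 of 28 cases by a small step (median 0.20, adjusted p = 0.000373; adjusted p = 0.968 with an estimated correlation). None passed singly by edgeR; Rps6 had a log2 fold change of 0.34 and Rpl8 of 0.28. Of 24 digestive enzyme genes, Try10 passed over all genes and Try10 and Sycn (0.66, adjusted p = 0.166 over all genes) adjusted over the list alone, in opposite directions. Of 12 genes of fatty acid synthesis and oxidation Fasn (−0.62) and Scd1 (−0.68) passed adjusted over the list alone and none over all genes. Neither the 12 tested core clock genes (median −0.09, adjusted p = 0.832) nor the 21 of the unfolded protein response (median 0, adjusted p = 0.95) passed with age in the 11 libraries.

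In all 12 libraries 9 lists passed camera, 6 higher in Old (digestive enzymes, acinar transcription factors and secretory machinery, plasma cells and immunoglobulins, regenerating genes, the unfolded protein response and ribosomal proteins) and 3 lower (clock output, fibroblasts and the proteasome). With an estimated correlation 0 lists passed in either set: in 12 libraries adjusted p = 0.566 with an estimated correlation for 7 of the 9, 0.659 for acinar transcription factors and 0.738 for the unfolded protein response. By fry, which asks whether a list's genes move on balance 1 way, 0 passed too. Young 4 h held the lowest summed CPM of digestive enzyme, acinar, unfolded protein response and ribosomal genes among the 12 libraries and the highest of proteasome genes, at 825 CPM against at most 447. Plasma cell and immunoglobulin genes summed to 592.6 CPM in Old 24 h, while the other Old libraries, at 64.6 to 139.4 CPM, lay within the Young range of 15.3 to 193 CPM, and the list did not pass without Old 24 h, nor without Young 4, 12 or 20 h or Old 4, 12 or 16 h. Regenerating and ribosomal genes passed whichever of the 12 was left out. Of the rest, digestive enzymes lost their call without Young 4 h, acinar and proteasome genes without Young 4 h or Old 4 h, and fibroblast genes without Young 16 h or Old 16 h. The unfolded protein response lost it without Young 4, 16 or 20 h or Old 4, 8, 16 or 20 h, and clock output genes without Young 4, 12, 16 or 24 h or Old 4, 8, 16, 20 or 24 h. In 12 libraries the count was 3 without Young 4 h and 4 without Old 4 h.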

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

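The test of digestive enzymes below, the tests of islet genes, and the test of Col3a1 without Young 4 h were chosen after the result they measure was seen, and so were the gene lists behind the others. A library was singled out when its gap to the nearest of its age was large against the range of the 6 by Dixon's test at 95%. Of 56 groups of values 17 passed this, and 8 of them were Young 4 h and 6 were Old 24 h. The groups included genes named for their values in these data, and some of these genes are also in a list. The rate of about 1 in 20 that chance gives for independent values therefore does not apply, and the 17 only describe the libraries.

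The library labelled Young 4 h stood apart from the other Young libraries in total counts (2.92M, next 1.32M), in genes detected (22594, next 15201), and in the Schwann cell and nerve list (646.4 CPM, next 7), which holds brain genes such as Gfap. Summed CPM of the central glia list was 26.9 times that of the highest other library (95% interval 20.6 to 35.8, counting error only) and of central neurons 81.3 times (58.7 to 116), as RNA or reads from central nervous tissue mixed into this library, at a step the data do not show, may give. More of the pancreas's own nerves and ganglia is argued against by peripheral nerve and ganglion genes at 2.13 times the highest other library (1.34 to 3.57) beside the 26.9 of glia, and a whole library of another tissue by digestive enzyme genes at 19.51% of counts. No biological explanation was tested, since no group in the design sets this library apart, and the hypothalamic peptide list, at 466 CPM against at most 205, does not name a brain region.

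Islet genes followed collection time, and the beta cell list stood highest in Old 16 h (1223.5 CPM, next 615.6). A shared 24 h order of times is a candidate explanation: without Young 4 h the real order ranked 1 of 60 by mean log F of the list (2.123 against at most 2.069), but it ranked 2 in all 12 libraries (1.818 against 1.831), 2 in Old and 11 in Young (a share of 0.183) without Young 4 h, and time of day as the source stays open. A share of islet tissue that differed between pieces cannot be told apart from it, because each time has 1 library per age. Over the 11 libraries Ins2 followed Gcg (Pearson r = 0.92, permutation p = 1e-04, adjusted 2e-04; Spearman rho = 0.91, permutation p = 0.00016, adjusted 0.00032; r = 0.93 without Old 16 h and Old 24 h) and beta cell genes other than hormones (r = 0.79, permutation p = 0.00365; rho = 0.73, permutation p = 0.0147; adjusted p the same; r = 0.56 without those libraries). These are 2 relations with 100000 two-sided resamples, and 91.8% of the counts of those beta cell genes were Ero1b, which acinar cells also express. Ins2 and Gcg had both passed the shared curve in these 11 libraries, so their correlation does not weigh 1 explanation against the other.

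Collagen genes were lower in Old: without Young 4 h the median log2 fold change was −0.97 for 7 genes (collagens and Sparc, 7 of 7 lower). The library labelled Young 4 h as the only source is argued against by these 7 genes, which were lower without it. The test of Col3a1 (−1.31 without it, −0.95 with it) could hardly fail, since that library lessened the fall of this gene. Sparc, at 244.81 CPM in that library, stood at −1.66 with it and −1.16 without. A lower share of fibroblasts in the Old pieces may contribute and cannot be told apart from lower collagen transcripts per cell: 6 fibroblast markers outside the matrix had a median of −0.44 (5 of 6 lower), a gap of 0.53 with a standard error of 0.3. Age itself, which the design names, stays open.

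Other values of Young 4 h that stood apart were LOC118568312, a gene whose function is not given in the sources used here, at 5.08% of counts (95% Wilson interval 5.05 to 5.1%, next 17.08%), Kcnma1 at 61.32 CPM (next 5.26), Camk2b at 154.77 CPM (next 63.93), Sparc at 244.81 CPM (next 84.33) and cytosolic ribosomal protein genes at 2892.8 CPM (next 4587.9). Reg3b stood at 66.14 CPM in Young 8 h (next 28.52). 1810007D17Rik stood at 35.75 CPM in Young 16 h (next 15.74). In Old 24 h, T and NK cell genes summed to 65.1 CPM (next 13.8), plasma cell and immunoglobulin genes to 592.6 (139.4), MHC class II genes to 456.4 (143.9), lymphoid stroma genes to 112.8 (25.5), neutrophil genes to 30.4 (4.4) and blood genes to 97.2 (14).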

How the results depend on the processing

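Fits without Young 4 h together with another change, or without both 4 h libraries, were chosen after the result was seen, and the rest were planned. With age, 2 lists that passed as higher in Old in 12 libraries turned to lower without passing: acinar transcription factors and secretory machinery without Young 4 h (adjusted p = 0.954) and with time as a block without both 4 h libraries (0.858), and the unfolded protein response without Young 4 h (0.95). With any 1 other library left out both stayed higher, with adjusted p down to 0.000481 and 0.000252 without Young 24 h. No other value compared here reversed. Of the values for single genes and lists 710 kept their side of the threshold, 109 passed it only under an alternative and 103 lost it, the cause not tested; RLE scaling and scaling without digestive enzymes moved no count by over 1.5 times. With no low count filter (28805 genes, a median log2 fold change of −0.122), counts were 67 for age (9 higher in Old), 648 for the rhythm across both ages, 1144 in Young, 14 in Old and 113 for the difference; with the stricter filter (11886 genes) 3 for age and 50 in Young. DESeq2 gave 5, 40, 45 and 4 for age, shared, Young and Old rhythm. For age, no time term gave 2 and a curve for each age 2. Times as a factor gave 3 for the shared rhythm. Separate fits gave 0 in Young (221 with an unadjusted p under 0.05) and 24 in Old.

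Leaving out 1 library gave 1 to 12 genes for age, 4 to 87 for the shared rhythm, 2 to 435 in Young, 0 to 44 in Old, 0 to 0 for the difference, and 3 to 12 lists; Young 4 h gave the 12, 87, 44 and 3, Young 24 h the 435 and Young 8 h the 12 lists. Without both 4 h libraries counts were 9, 37, 10, 37 and 4 for age, shared, Young, Old and the difference; without Young 4 h and Old 24 h they were 16, 71, 9, 24 and 1. Without Young 4 h, DESeq2 gave 14, 58 and 20 for age, shared and Old, limma-voom 10, 71, 7 and 27 for age, shared, Young and Old, and no time term 11 for age. Leaving a further library out of the 11 gave a difference in rhythm for 3 genes without Young 24 h, 4 without Old 4 h, 4 without Old 12 h, 2 without Old 16 h and 1 without Old 24 h. For lists, an estimated correlation and fry gave 0 (0 and 2 lists with an unadjusted p under 0.05).

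Libraries of the same time correlated at 0.052 to 0.137 after group means were removed, against a median of −0.013 for other times, and 4 of 6 Young libraries correlated best with their own time. Since 3 of 6 pairs lay above 0.1, not all, and no label pairs the mice, the libraries were not treated as pairs. With time as a block age gave 1 gene and 10 lists, and without both 4 h libraries 11 genes and 4 lists. The floor of 3 counts lies at about 3 CPM in the 11 libraries, but depth limited genes above it too. Bhlhe41, at a mean of 9.02 CPM in Young and 9.12 CPM in Old, had too few counts to be tested. The self-test simulated no library that stands apart as Young 4 h does, so its shares for 12 libraries do not bound what could be seen. In Old with 12 libraries Arntl missed the threshold at a log2 amplitude of 3.16 (adjusted p = 0.141 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).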

Other observations

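No test of an explanation in this part was chosen after its result was seen, but the repeated counts without Young 4 h were.

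The library labelled Old 24 h was rich in transcripts of several immune cell types at once. B cell genes summed to 74.6 CPM against at most 34.7 in any other library, complement genes to 1011 CPM against at most 538, and MHC class I genes, which present antigen on most cells, to 308.9 CPM against at most 187. The lowest fibroblast (173.4 CPM), macrophage (36.3 CPM) and MHC class II (28.9 CPM) sums of the 12 libraries were all in Old 16 h, where the beta cell list was highest.

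The library labelled Old 20 h stood at the Young level for Reg2, Reg3a, Reg3b and Itih4, but not for 1810007D17Rik (91.1 CPM, at most 35.8 in Young), Cobl (68.3 CPM, at most 40.1) or Kcnma1 (27.1 CPM, at most 5.26 in the 5 Young libraries other than Young 4 h). Its Reg2 was 37.7 CPM against 1111 to 4935 CPM in the other 5 Old libraries, Reg3a had 0 counts, Reg3b stood at 19.3 CPM and Itih4 at 17.5 CPM. The list sum of regenerating and acute phase genes was 1791 CPM there, against 3210 to 8099 in the other Old libraries and 1748 to 3326 in Young.

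Random splits of the libraries asked whether chance can be excluded for each count. With 12 libraries, 7 of 100 splits gave as many genes as the real split by age (1), so chance cannot be excluded, and the highest other split gave 976, which points to a structure of the samples: the splits with most calls put Young 4 h with libraries of 12 and 16 h. Over 11 libraries 4 of 100 splits, the real one among them, gave as many as the real 12, and 1 other split gave 29. Only 100 of 462 possible splits were drawn, and they do not balance collection times between the sides. The set of 11 was also chosen after its values were seen, so chance cannot be excluded here. For gene lists, 36 of 100 splits gave as many as the real 9 with 12 libraries (highest other 19), and 55 of 100 as many as the real 3 without Young 4 h (highest other 13), so chance cannot be excluded for either. All 32 swaps of ages within times gave at least the real count of 0 genes with a different curve by edgeR (highest other 0), a count that no swap can undercut.

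Orders of collection times other than the real one gave fewer genes with a curve shared by both ages. The real order gave 9 genes with 12 libraries and the highest of the 59 others 6, and without Young 4 h it gave 87 against at most 45. With 12 libraries the real 3 in Young was the highest count, reached in 3 of 60 orders. The real 0 in Old by edgeR was matched or passed by all 60 (highest 1). In Old with the real order 201 genes had an unadjusted p under 0.05 where chance gives 290, DESeq2 gave 4 and limma-voom 0. In Young without Young 4 h the real 10 was matched or passed in 5 of 60 orders (highest 17), and in Old the real 44 stood above all others (highest 25).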
